A study of Arabidopsis thaliana with 48 samples.

How the data were processed

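Total RNA from roots of Arabidopsis thaliana seedlings was measured on 48 single-channel Affymetrix expression arrays. The 6-day-old seedlings had grown on a nylon mesh and were moved with it to control medium or to medium with 1 µM of the auxin indole-3-acetic acid (IAA). Per the labels, roots were taken after 0 h (fewer than 5 minutes on the medium), 0.5, 1, 2, 4, 8, 12 and 24 h, with 3 arrays for each of the 16 combinations of medium and time.

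The deposited values are log2 intensities, 1 per probe set and array, for 22810 probe sets. The unit was read from the values: the maxima of the arrays lay between 14.1 and 15.1, and the bacterial and phage spike-in probe sets rose in their known order, from a mean of 9.02 for bioB to 10.1 for bioC, 12.0 for bioD and 14.0 for cre. The array means lay between 7.70 and 7.71 while the medians ran from 7.46 to 7.64 and the standard deviations from 1.79 to 1.87, so the authors' values share a mean and are not quantile normalized as deposited. The method of summary and normalization is not given in the sources used here. Of all 1094880 values, 54 were exactly 0, in 6 probe sets. No pair of arrays held identical values, and correlations between arrays ran from 0.936 to 0.997. Arrays have no read depth, and 3 arrays per group limit the precision of every value.

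The 64 Affymetrix control probe sets were left out, and 22746 probe sets were tested without a filter on low values. Probe sets were joined to genes by the gene table of this array set and to symbols by the RefSeq gene table of the assembly TAIR10.1. The gene table named exactly 1 gene for 13523 of the tested probe sets (59.5%), several genes for 493 and did not list 8730, so genes are named only from the first set. A gene with several probe sets was represented by the one with the highest mean. Genes without a symbol are given by locus.

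A mean for each of the 16 groups was fitted to all 48 arrays in 1 model with limma 3.58.1 (lmFit and eBayes, R 4.3.3), with 32 residual degrees of freedom before moderation. The comparisons were IAA minus control at each time, a moderated F test over the 7 such contrasts from 0.5 to 24 h, the control arrays of each later time against those of 0 h with an F test over these, and the change of the IAA effect from 0.5 to 4 h and from 2 to 24 h as interactions. Every p-value of a single gene below is limma's, two-sided and adjusted by Benjamini-Hochberg over all probe sets within its contrast, and a result passed at an adjusted p under 0.05. Errors of log2 changes are standard errors of the fit with n = 3 arrays in each group, and errors of group means are standard deviations (SD). Kinetic classes took the probe sets past the F test with a fold of at least 2 at 1 time or more and sorted them by the time of their largest absolute change (the peak) and by the first time past the test in that direction (the onset).

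The comparisons, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule named GH3.3 and LBD29 as a check of the labels, since IAA1, IAA5 and IAA19, also in it, have no probe set with exactly 1 gene in the gene table. It further named the 10 largest rises and 10 largest falls at any time, the 3 largest in each direction at each time with all 3 IAA arrays beyond all 3 control arrays, 4 in each direction for each interaction, and up to 4 members of each list that passed the F test, or up to 2 with the largest change where none passed. The 21 lists held 445 members, of which 72 had a probe set that names 1 gene. Of the members, 394 were written out, 5 of these were left out because the tables pair their locus with another symbol, and 56 were added by symbol pattern. Members with such a probe set are called measured here. The others could not be named and may lie among the probe sets that the gene table does not list. The SAUR genes, the auxin response factors and receptors, and the nitrate response genes had 0 measured members and were not tested. Lists of at least 3 measured members were tested at each time with camera at its preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over all lists and times.

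Replicate numbers were not treated as pairs, because fewer than all control and IAA arrays of the same number and time deviated together. Of 24 such pairs, 19 deviated together (correlation over 0.1), so spread shared by a replicate number stayed in the residuals of the main fit. With the replicate number as a block, both interaction counts rose by more than 1.5 times. Alternatives were quantile normalization, centring on the median, a filter on low values, the replicate number as a block, an intensity trend with robust estimation, each array and each replicate number left out in turn, a fold of at least 2 in addition, a fit of only the 6 arrays of a time, other references, and another probe set or test for the lists. The 4 arrays farthest from their group means were left out together as an alternative chosen after seeing the data. These were control 0 h, IAA 1 h and IAA 2 h of replicate 3 and IAA 24 h of replicate 2. As they were chosen by their large deviations, leaving them out lowers the pooled spread used at every time.

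The tests were tested on simulated data with the spread of each probe set in these arrays, in which 200 probe sets were changed. The noise was drawn independently for each value. Deviations shared by arrays of 1 replicate number or by genes were not simulated, so the rates below do not cover them. At 2 h, 84% of changes of log2 1 and 37% of changes of log2 0.5 were found, with 7 unchanged probe sets called. For the F test and the interaction the changes were likewise made in the IAA arrays of 2 h alone, and changes lasting over several times were not simulated. The F test found 67% and 13%, with 10 unchanged probe sets called beside 80 changed ones. The interaction found 55% and 13% (2 unchanged beside 68 changed), and the F test of the control course 83% and 29% for changes at 24 h (4 beside 112). With 20 genes in each list, the list test called the 1 shifted list and 0 of 20 others, and shorter lists, such as most of those tested here, were not simulated. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.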

Results

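Transcript levels were measured in roots of 6-day-old Arabidopsis seedlings on control medium or on medium with 1 µM IAA, at 8 times from 0 to 24 h. Each of the 16 groups held 3 arrays, and each array gave log2 values for 22746 probe sets besides the control probe sets. The study set out to follow the kinetics of auxin-responsive transcripts, so each time point on IAA was compared with control medium of the same time. Genes could be named for 59.5% of the probe sets, and statements about gene groups cover those alone.

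The comparison at 0 h gives the background of the others, since the roots had been on either medium for fewer than 5 minutes. GH3.3, which encodes an enzyme that conjugates IAA to amino acids, stood at 7.68 ± 0.24 on IAA and 8.25 ± 0.39 on control medium (log2, SD, n = 3). LBD29, a transcription factor of lateral root formation, stood at 6.89 ± 0.18 and 7.12 ± 0.53. Neither difference passed (limma adjusted p = 1 for both). With limma, 0 of 22746 probe sets passed, and 181 had an unadjusted p under 0.05, where 1137 are expected by chance. The test thus ran below its nominal rate, and 0 calls do not exclude a difference. The expansin and XTH list, cell wall proteins that loosen or remodel the wall, had a mean log2 change of 0.13 that passed camera (adjusted p = 0.0127), with adjusted p = 0.154 with an estimated correlation.

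At 0.5 h on IAA, GH3.3 was 30.7-fold higher (log2 4.94 ± 0.555, n = 3 per group, limma adjusted p = 1.72e-07) and LBD29 17.5-fold higher (4.13 ± 0.25, 4.91e-14). WES1, which is GH3.5 of the same enzyme family as GH3.3, was 7.82-fold higher (2.97 ± 0.235, 6.27e-11). The lateral root factor LBD16 and the homeodomain-leucine zipper factor HAT2 had their largest rise at this time, 6.03-fold and 5.02-fold. The largest falls were those of AT4G25250 (4.27-fold, log2 -2.09 ± 0.417), AT3G19680 (2.71-fold, -1.44 ± 0.351) and the expansin EXPB1 (2.50-fold, -1.32 ± 0.319). In all, 211 probe sets rose and 57 fell, 113 of them by a fold of at least 2. The 268 calls became 153 without control 0.5 h replicate 1, 142 without IAA 0.5 h replicate 1, 161 without control 0.5 h replicate 2 and 162 without IAA 0.5 h replicate 2. They became 65 without replicate 2, 79 without replicate 1 and 559 without replicate 3. Without the 4 arrays farthest from their group means, the count was 427. None of these 4 is an array of 0.5 h, so the log2 changes at 0.5 h were the same and only the pooled spread differed. Leaving out single arrays ended the calls of AT4G25250 (control replicate 1, adjusted p = 0.0602), AT3G19680 (IAA replicate 1 or 2 or control replicate 2, 0.165 to 0.433) and EXPB1 (replicate 1 or 2 of either medium, 0.0536 to 0.272).

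At 1 h the same 3 genes led the rises. GH3.3 was 22.4-fold higher (log2 4.49 ± 0.555, adjusted p = 1.17e-06), LBD29 10.9-fold (3.45 ± 0.25, 1.24e-11) and WES1 8.77-fold (3.13 ± 0.235, 1.24e-11). AT4G25250 was 4.63-fold lower (-2.21 ± 0.417), AT5G66815 3.49-fold lower (-1.80 ± 0.245) and AT1G05060 3.47-fold lower (-1.80 ± 0.457). YUC6, a flavin monooxygenase of auxin biosynthesis, reached its lowest point relative to control, 1.98-fold lower (-0.99 ± 0.103, adjusted p = 2.92e-08). In all, 304 probe sets rose and 138 fell, 186 of them by a fold of at least 2, and 175 of the 268 called at 0.5 h passed again in the same direction. The count of 442 became 256 without IAA 1 h replicate 1 and 93 without replicate 1, and the GH3.3 call was lost when only the 6 arrays of 1 h were fitted (adjusted p = 0.0906). The AT1G05060 call was lost without control 1 h replicate 1 or 3 or without IAA 1 h replicate 3 (adjusted p 0.119 to 0.257), and that of AT4G25250 without replicate 1 (0.368).

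At 2 h the rises of GH3.3 (47.8-fold, log2 5.58 ± 0.555), LBD29 (17.4-fold, 4.12 ± 0.25) and WES1 (14.8-fold, 3.89 ± 0.235) stood beside peaks of IAA29 and IAA30, repressors of auxin signalling, and of PUCHI, an AP2-type transcription factor of lateral root formation. IAA29 was 8.66-fold higher (3.12 ± 0.361, adjusted p = 9.91e-08), PUCHI 6.17-fold (2.63 ± 0.265, 5.57e-09) and IAA30 4.23-fold (2.08 ± 0.225, 2.35e-08). AT4G25250 was 9.93-fold lower, AT1G64590 8.98-fold lower and AT5G66815 8.85-fold lower, with AT5G66815 at 5.43 ± 0.20 against 8.57 ± 0.14 (log2, SD, n = 3). The calls grew to 1238 rises and 856 falls, 501 of them by a fold of at least 2. The 2094 calls became 1002 without IAA 2 h replicate 1, 1315 without IAA 2 h replicate 2, 362, 630 and 3248 without replicates 1, 2 and 3, and 3433 without the 4 arrays farthest from their group means, 1 of which is IAA 2 h replicate 3. The IAA29 call was lost when only the 6 arrays of 2 h were fitted (adjusted p = 0.0571).

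**Figure D1:**
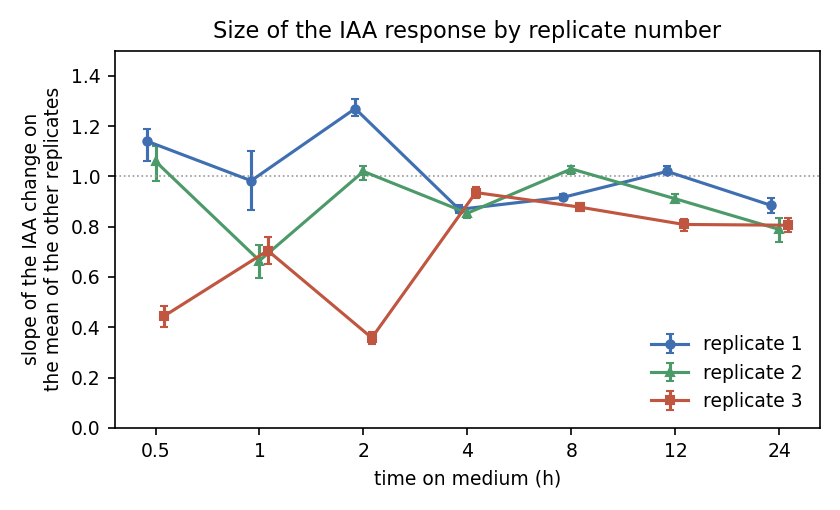
Slope (no unit) of the log2 IAA change in 1 replicate number on the mean change of the other replicate numbers, by time in hours, over the probe sets called without that replicate; bars are 95% bootstrap intervals over probe sets. Replicate 3 had slopes of 0.444, 0.705 and 0.358 at 0.5, 1 and 2 h and 0.806 to 0.936 at 4 h and later, and replicates 1 and 2 ranged from 0.665, in replicate 2 at 1 h, to 1.27.

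At 4 and 8 h GH3.3, LBD29, WES1 and GH3.1 reached their largest rises. GH3.3 peaked at 68.5-fold at 4 h (log2 6.10 ± 0.555, adjusted p = 2.05e-10), and AT5G48430 was 22.9-fold higher at that time (4.52 ± 0.733, 2.02e-05). At 8 h LBD29 peaked at 29.4-fold (4.88 ± 0.25), WES1 at 22.5-fold (4.49 ± 0.235) and GH3.1 at 17.3-fold (4.12 ± 0.32). PR-1-LIKE, of the pathogenesis-related family, was at that time 52.7-fold higher (5.72 ± 0.392, 1.4e-13). AT4G25250 fell 12.9-fold at 4 h (-3.69 ± 0.417) and 12.1-fold at 8 h, AT5G04120 10.8-fold at 4 h and AT3G53980 9.26-fold at 4 h. At 8 h AT2G41730 was 12.7-fold lower (-3.66 ± 0.832, adjusted p = 0.00168), AT3G59370 11.2-fold lower (-3.49 ± 0.316, 1.15e-10) and the peroxidase gene AT3G01190 9.16-fold lower (-3.20 ± 0.257, 5.77e-12). At 4 h 2213 probe sets rose and 1614 fell, 896 by a fold of at least 2. At 8 h 1923 rose and 1462 fell, 893 by a fold of at least 2. Of the 3827 called at 4 h, 2055 passed at 8 h in the same direction and 2 in the opposite one. Without replicate 1 the counts were 1808 at 4 h and 1444 at 8 h, and without replicate 2 they were 2406 and 1723. Without replicate 1 the calls of AT5G04120 at 4 h (adjusted p = 0.0932) and of AT2G41730 (0.0897) and AT2G21640 (0.0717) at 8 h were lost.

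At 12 and 24 h a further set of genes led. PR-1-LIKE was 91.0-fold higher at 12 h (log2 6.51 ± 0.392, adjusted p = 2.42e-15) and 94.7-fold at 24 h (6.57 ± 0.392, 2.47e-15). AT2G19970 rose 34.2-fold and 41.3-fold (5.09 and 5.37, both ± 0.466), AT5G14650 38.6-fold at 12 h (5.27 ± 0.414) and AT5G47550 34.8-fold at 24 h (5.12 ± 0.238). At 12 h AT5G04120 was 13.9-fold lower (-3.80 ± 0.877, adjusted p = 0.00245), AT2G41730 11.7-fold lower and AT4G11210, a dirigent protein gene, 9.03-fold lower. At 24 h AT2G41730 was 8.10-fold lower (-3.02 ± 0.832, adjusted p = 0.0187), AT2G21640 7.13-fold lower (-2.83 ± 0.688, 0.00655) and AT5G09570 5.72-fold lower (-2.52 ± 0.737, 0.0286). Their IAA arrays of 24 h varied widely, with SDs of 2.28, 1.57 and 1.42 (log2, n = 3). All 3 are among the 12 genes grouped after the data were seen, described below. The median change of the 12 at 24 h was -1.84, -0.4 and -2.2 in replicates 1, 2 and 3. IAA 24 h replicate 2 is 1 of the 4 arrays farthest from their group means. The counts fell to 1362 rises and 1121 falls at 12 h, 801 by a fold of at least 2. They fell further to 862 rises and 730 falls at 24 h, 522 by a fold of at least 2. Without replicate 1 the counts were 993 and 613 and without replicate 2 they were 1348 and 759, and the 12 h calls of AT5G04120 (adjusted p = 0.093), AT2G41730 (0.147) and AT4G11210 (0.061) were lost without replicate 1, that of AT2G41730 also without replicate 2 (0.0616). The 24 h calls of AT2G41730, AT2G21640 and AT5G09570 were lost without IAA 24 h replicate 1 or replicate 3 (adjusted p 0.054 to 0.167), that of AT5G09570 also without control 24 h replicate 1 (0.0591), 2 (0.058) or 3 (0.118), and that of AT2G41730 without control 24 h replicate 2 (0.0568) or 3 (0.0599).

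**Figure D2:**
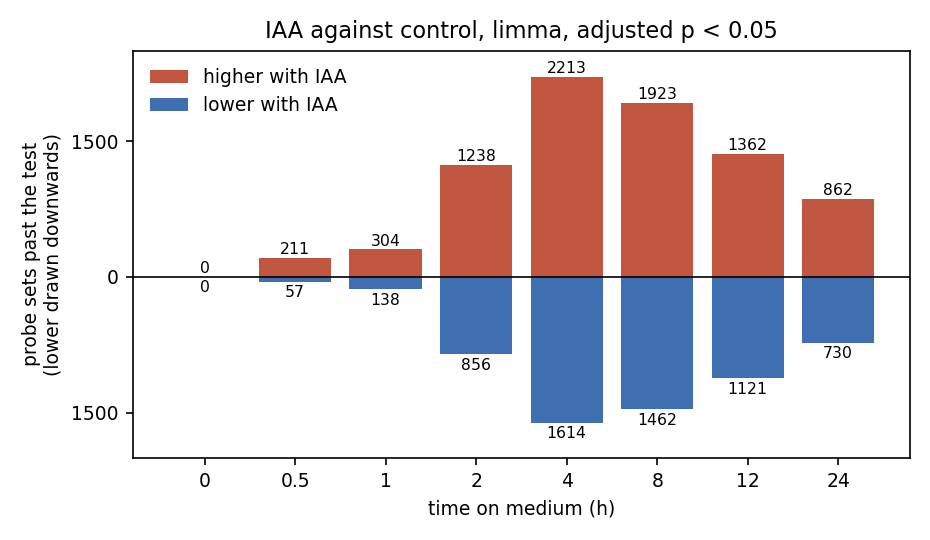
Number of probe sets past the test (vertical axis) on IAA against control medium at each time in hours, higher with IAA drawn upwards and lower drawn downwards. The bars run from 0 at 0 h to 2213 higher and 1614 lower at 4 h and 862 higher and 730 lower at 24 h.

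Across the 7 times from 0.5 to 24 h, 6429 probe sets passed the F test, 28.3% of those tested, and 1597 of them also reached a fold of 2. PR-1-LIKE, GH3.3 and LBD29 were joined among the 10 largest rises by AT5G52390 (28.6-fold at 12 h, log2 4.84 ± 0.295), the expansin EXPB2 (log2 4.64 ± 0.251 at 12 h), the pectate lyase gene AT1G67750 (23.6-fold at 12 h, 4.56 ± 0.212) and AT1G30760 (22.9-fold at 12 h, 4.52 ± 0.199). The 10 largest falls included AT5G04120, AT4G25250, AT2G41730 and AT3G59370, then AT3G53980 (9.88-fold at 8 h), AT4G11210 (9.77-fold at 8 h), AT3G01190, AT1G64590, AT5G66815 and AT2G21640 (8.76-fold at 8 h). Among probe sets the gene table does not list, the largest rises were 5.78 ± 0.206 at 12 h and 5.49 ± 0.494 at 24 h, and the largest falls -4.00 ± 0.335 at 8 h and -3.64 ± 0.259 at 4 h (log2). The control mean of AT5G14650 at 12 h (6.01), the IAA means of AT4G25250 at 2 and 4 h (6.04 and 6.07), AT3G59370 at 8 h (5.78) and AT5G66815 at 2 h (5.43), and the control mean of the unlisted probe set with the rise of 5.78 (5.90) lay below the lower quartile of every array (6.11 to 6.30), so their folds rest on values not shown to lie above background. The IAA mean of AT4G25250 at 8 h (6.12) and the control means of IAA29 at 2 h (6.22) and GH3.1 at 8 h (6.23) lay within the range of these quartiles. Their folds at these times are likewise not shown to be clear of background. The F test count was 2741 without replicate 1 and 3556 without replicate 2.

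**Figure D3:**
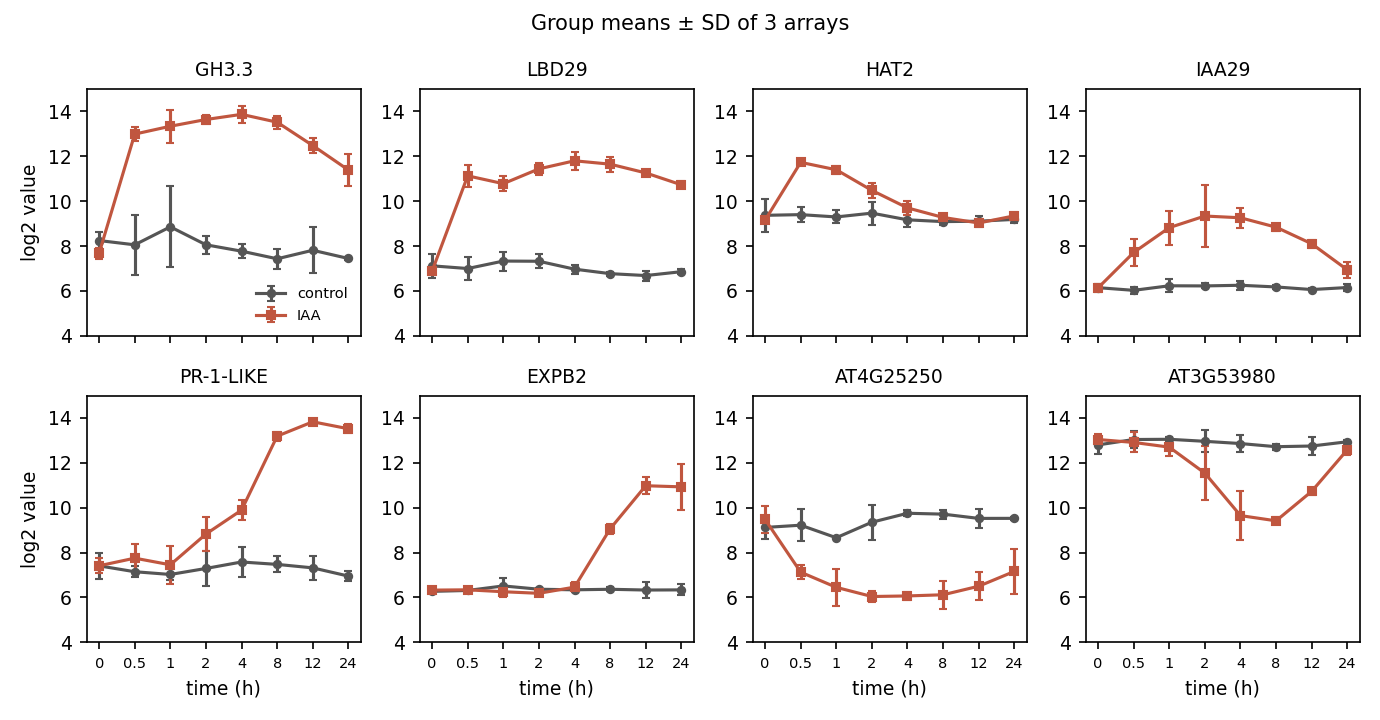
Mean log2 value ± SD of 3 arrays (vertical axis) by time in hours for 8 genes, IAA and control medium drawn as separate lines. GH3.3 and LBD29 were high on IAA from 0.5 h, HAT2 returned towards control after 1 h, and PR-1-LIKE and EXPB2 rose late. AT3G53980 was 9.42 at 8 h on IAA against 12.7 on control medium.

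Peaks of the 1597 probe sets spread over the whole course. HAT2 and LBD16 peaked at 0.5 h, IAA29 and PUCHI at 2 h, GH3.3 at 4 h, LBD29 and WES1 at 8 h, EXPB2 at 12 h and PR-1-LIKE at 24 h. A neighbouring time came within the standard error of the peak for GH3.3 (log2 6.08 at 8 h), LBD29 (4.83 at 4 h), EXPB2 (4.59 at 24 h) and PR-1-LIKE (6.51 at 12 h). The same held for HAT2, with 2.33 at 0.5 h and 2.1 at 1 h (standard error 0.243). The exact peak times of all these genes are therefore not resolved. The largest change was upward at 0.5 to 2 h in 148 probe sets, at 4 to 8 h in 359 and at 12 to 24 h in 333, and downward in 96, 438 and 223. The first time past the test in that direction was 2 h for 249 upward and 271 downward probe sets, more than at any other single time, and 0.5 h for 130 and 20. In all 57 probe sets were called at every one of the 7 times, each in 1 direction, and 114 were called higher at 1 time and lower at another. Without the 4 arrays farthest from their group means, the early peaks numbered 286 upward and 264 downward.

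Of 7 measured Aux/IAA repressors, 4 rose and 3 did not pass the F test, with IAA29, IAA30 and IAA18 (3.24-fold at 8 h, log2 1.70 ± 0.169) the largest and IAA20 1.59-fold higher at 1 h (0.67 ± 0.131, adjusted p = 0.00163). The list passed camera at 0.5, 1, 2, 4 and 8 h, with adjusted p from 1.89e-09 to 0.000545 and, with an estimated correlation, up to 0.0333. Of 6 measured genes of the list for IAA conjugation and oxidation, 4 rose, namely GH3.3, WES1, GH3.1 and GH3.17 (3.58-fold at 12 h, 1.84 ± 0.254). The other 2, GH3.9 and UGT84B1, did not pass. The oxidation genes DAO1 and DAO2 were not among the 6, so the list covers conjugation alone. GH3.17 was lower at 2 h (-0.95, adjusted p = 0.0125). This list passed camera at all 7 times after 0 h, its median change rising from 1.04 at 0.5 h to 2.68 at 8 h and standing at 1.95 at 24 h. Of 3 auxin biosynthesis genes, YUC6 fell and 2 did not pass the F test, and 2 passed adjusted over the list alone. That list passed camera at 0.5, 1 and 2 h as lower (adjusted p = 0.0132, 4.66e-05 and 0.00236, and 0.044, 0.00165 and 0.0149 with an estimated correlation). The IAA20 call was lost without replicate 1 (adjusted p = 0.128), when only the 6 arrays of 1 h were fitted (0.194) and with the 0 h effect subtracted (0.209), and the biosynthesis list at 0.5 h was lost without replicate 3 (adjusted p = 0.394).

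All 4 measured lateral root and meristem regulators rose: LBD29, PUCHI, LBD16 and CR4, the receptor kinase ACR4, which was 1.31-fold higher at 8 h (log2 0.39 ± 0.0875, adjusted p = 0.0014, and 0.0809 without replicate 2). Of the 4, only 1 was called at 12 h and 1 at 24 h. Their list passed camera at all 7 times after 0 h, with the largest median change of 2.25 at 2 h. HAT2 was the 1 measured HD-ZIP II factor and rose. Of 27 expansins and XTHs, 13 passed the F test and 14 did not. Of the 13, 5 had their largest change upward (3 of these also past the test at that time) and 8 downward (all 8 past it). EXPB2 rose, as did EXPA4 (3.54-fold at 4 h, 1.82 ± 0.317), while EXPB1 (5.71-fold at 8 h, -2.51 ± 0.319) and XTH21 (4.24-fold at 2 h, -2.09 ± 0.303) fell. The list passed camera as lower at 2 h (mean -0.33, adjusted p = 0.00126), with adjusted p = 0.0573 with an estimated correlation. Adjusted over the list alone, 14 of the 27 passed, and the count adjusted over the list alone was 4 for the Aux/IAA repressors, 4 for conjugation, 4 for the lateral root list and 1 for HD-ZIP II.

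Other lists held few measured members. Of 4 pectin genes, PMEPCRF (1.74-fold lower at 4 h, log2 -0.80 ± 0.2, adjusted p = 0.0504 without replicate 3) and PME61 passed the F test, and adjusted over the list alone it was again 2. The largest change of PME61, 1.26-fold lower at 12 h, did not pass alone (limma adjusted p = 0.0913). PMEAMT, matched by its symbol, is a phosphoethanolamine methyltransferase and not a pectin enzyme, and it did not pass. Of 3 cell division genes, PRL, which is the replication licensing factor MCM7, rose 1.75-fold at 4 h (0.81 ± 0.127) and the kinase AUR1 1.49-fold at 8 h (0.57 ± 0.13, adjusted p = 0.0737 without replicate 1 and 0.0882 with the 0 h effect subtracted), 2 also adjusted over the list alone. That list passed camera at 8 h (mean 0.46, adjusted p = 0.018), with adjusted p = 0.148 with an estimated correlation. Of 2 root hair genes, the expansin EXPA7, also in the expansin list, passed the F test (limma adjusted p = 0.0225) with a largest change of 1.87-fold at 1 h that did not pass alone (adjusted p = 0.172). GSO1, a receptor kinase of the endodermal barrier and the 1 measured gene of its list, fell 1.59-fold at 24 h (-0.67 ± 0.16, adjusted p = 0.00561), with adjusted p = 0.0567 without control 24 h replicate 1. Of 3 shoot and photosynthesis markers, LHCB4.1 fell 1.59-fold at 4 h (-0.67 ± 0.203, adjusted p = 0.0178), with adjusted p = 0.0596 without control 4 h replicate 2 and 0.105 without IAA 4 h replicate 3. The marker list had a mean of 0.29 at 0.5 h (camera adjusted p = 0.036, and 0.251 with an estimated correlation).

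None of the measured genes of 7 lists passed the F test with limma. The values at their largest change were 1.45-fold for WAG2 of auxin transport, 1.24-fold for EIN3 of ethylene signalling, 1.47-fold lower for RR16 and 1.28-fold lower for ARR15 of cytokinin signalling (both with an IAA mean below that quartile), 1.62-fold for GID1B and 1.24-fold for GID1A of gibberellin perception, 1.43-fold for UGT78D1 and 1.32-fold lower for UGT78D2 of flavonoid synthesis, 2.33-fold lower for STZ of the touch and wound list and 1.13-fold for GI of the clock. Adjusted over the list alone, EIN3 passed as 1 of 1, both cytokinin genes as 2 of 2 and 1 of the 2 gibberellin genes. In a list of 1 gene this adjusts nothing, and in a list of 2 genes little. Of all 22746 probe sets, 8444 had an unadjusted F test p under 0.05, so these passes say little about the lists. Camera called 26 of 72 pairs of list and time in the IAA effect, 22 with an estimated correlation and 31 with fry. These pairs include those of 0 h, where the expansin and XTH list was among the 26.

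On control medium alone, GH3.3 stood between 7.43 ± 0.45 at 8 h and 8.86 ± 1.80 at 1 h, and LBD29 between 6.69 ± 0.22 at 12 h and 7.33 ± 0.42 at 1 h (log2, SD, n = 3). The comparison with control roots of 0 h shows which transcripts moved after the transfer without added IAA. With limma, 0 probe sets passed the F test over the 7 later times, 480 had an unadjusted p under 0.05, and the smallest adjusted p was 0.732. Each single control contrast also gave 0, with 336 to 713 probe sets at an unadjusted p under 0.05. All these numbers lay below the 1137 expected by chance. The tests thus ran below their nominal rate, and 0 calls do not exclude changes on control medium. Camera called 0 of 63 pairs of list and time in the control course. The F test gave 2 probe sets without control 1 h replicate 1 and 1 without control 12 h replicate 2, and the list test gave 7 pairs without replicate 3.

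The change of the IAA effect from 0.5 h to 4 h shows which log2 effects differed between these times. AT2G28690 went from 0.63 at 0.5 h to 3.67 at 4 h (difference in log2 3.04 ± 0.403, adjusted p = 7.2e-06), AT5G65320 from 0.33 to 2.94 (2.61 ± 0.506), AT1G67750 from 0.10 to 2.66 (2.56 ± 0.3) and AT1G30760 from -0.0014 to 2.52 (2.52 ± 0.282). AT3G53980 went from -0.13 to -3.21 (-3.08 ± 0.554, adjusted p = 0.000527) and AT4G30460 from 0.02 to -2.79 (-2.82 ± 0.497). The dirigent protein genes AT4G11190 and AT4G11210 changed by -3.23 ± 0.928 and -3.16 ± 0.917 (adjusted p = 0.0357 and 0.0384). In all the signed log2 effect moved upward in 739 probe sets and downward in 282. The 1021 calls became 265, 245 and 588 without replicates 1, 2 and 3, 679 without IAA 4 h replicate 2 and 1567 without the 4 arrays farthest from their group means. None of these 4 is an array of 0.5 or 4 h, so only the pooled spread differed there. With the replicate number as a block the count was higher, as given below. Leaving out single arrays of these times ended the call of AT4G11190 in 8 cases, all but IAA 0.5 h replicate 1, control 4 h replicates 1 and 2 and IAA 4 h replicate 2 (adjusted p 0.0519 to 0.121), and that of AT4G11210 in 10, all but IAA 0.5 h replicate 1 and control 4 h replicate 2 (0.0514 to 0.124), and those of AT5G65320 (0.0665) and AT3G53980 (0.0584) were lost without replicate 2. Without replicate 1 the adjusted p was 0.192 for AT4G11190 and 0.214 for AT4G11210.

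The change from 2 h to 24 h asks the same of a later pair of times. PR-1-LIKE went from 1.53 at 2 h to 6.57 at 24 h (difference in log2 5.03 ± 0.555, adjusted p = 7.78e-08), EXPB2 from -0.18 to 4.59 (4.77 ± 0.355, 7.87e-12), AT2G19970 from 1.28 to 5.37 (4.09 ± 0.659, 9.6e-05) and the sugar transporter gene SAG29 from 0.10 to 4.04 (3.93 ± 0.219, 3.25e-15). IAA29 went from 3.12 to 0.79 (-2.33 ± 0.511, adjusted p = 0.00615). BHLH101, a transcription factor of iron deficiency, went from 0.38 to -2.29 (-2.66 ± 0.685, 0.0247), UGT72E1 from 0.52 to -2.03 (-2.55 ± 0.686, 0.0344) and AT1G51890 from 0.58 to -1.66 (-2.24 ± 0.587, 0.0278). In all the signed log2 effect moved upward in 345 probe sets and downward in 233. The 578 calls became 139 without replicate 1, 310 without replicate 2, 362 without IAA 2 h replicate 1, 381 without control 24 h replicate 3, 383 without IAA 24 h replicate 3, 884 without IAA 2 h replicate 3 and 1343 without the 4 arrays farthest from their group means. The replicate number as a block also raised this count, as given below. Single arrays ended the calls of BHLH101 (IAA 2 h replicates 1 and 2, IAA 24 h replicate 2, control 2 h replicate 3 and control 24 h replicate 3, adjusted p 0.0534 to 0.104), UGT72E1 (the same 5 and control 2 h replicate 1, control 24 h replicate 2 and IAA 24 h replicate 3, 0.0524 to 0.152) and AT1G51890 (IAA 2 h replicate 1, IAA 24 h replicates 1 and 3, control 2 h replicate 3 and control 24 h replicates 2 and 3, 0.0534 to 0.118), and that of IAA29 was lost without replicate 1 (0.329) or 2 (0.258). Without replicate 1 the adjusted p was 0.277 for BHLH101, 0.384 for UGT72E1 and 0.332 for AT1G51890.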

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

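The tests of the replicate 3 arrays, of the 12 grouped genes and of the plastid transcripts were chosen only after the results were seen, as was the count of regroupings that leave the IAA groups intact; the regroupings of the times were drawn again, each counted once, and the bounds for the exchanged arrays and for the control arrays were set again, and a test of series in the 12 genes was replaced by that of array variation, after a first outcome had been seen.

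The IAA effect differed between times in the test of the difference itself, for 1021 probe sets between 0.5 and 4 h and for 578 between 2 and 24 h. By that test the signed log2 effect moved upward from 0.5 to 4 h for AT2G28690 by 3.039, AT5G65320 by 2.607, AT1G67750 by 2.564 and AT1G30760 by 2.521, and moved downward for AT4G11190 (-3.229), AT4G11210 (-3.155), AT3G53980 (-3.082) and AT4G30460 (-2.815). From 2 to 24 h it differed for PR-1-LIKE by 5.032, EXPB2 by 4.77, AT2G19970 by 4.089 and SAG29 by 3.933, and for BHLH101 by -2.662, UGT72E1 by -2.547, IAA29 by -2.325 and AT1G51890 by -2.242. Single arrays ended the calls of AT4G11190 (adjusted p up to 0.121), AT4G11210 (0.124), BHLH101 (0.104), UGT72E1 (0.152) and AT1G51890 (0.118). Leaving out whole replicates ended those of IAA29 (without replicate 1, 0.329, or 2, 0.258) and, without replicate 2, of AT5G65320 (0.0665) and AT3G53980 (0.0584). It also ended those of AT4G11190 (adjusted p up to 0.192), AT4G11210 (0.214), BHLH101 (0.289), UGT72E1 (0.384) and AT1G51890 (0.332). Of 100 regroupings of the times within each medium, drawn from 200 and the real one included, 10 gave as many calls for 0.5 against 4 h (highest other 1906) and 11 for 2 against 24 h (highest other 1939). All 9 and 10 other regroupings as large left the IAA groups intact and exchanged control arrays only, so they kept the difference between the IAA arrays and the test decides nothing about chance. With the IAA groups mixed, the highest counts were 0 and 239. The highest intact one for 2 against 24 h was several times the real count, which points to a structure among the control arrays.

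The replicate 3 arrays showed a smaller IAA change at 0.5 and 2 h, with slopes on the other replicates of 0.444 and 0.358, against 0.806 to 0.936 at 4 h and later. At 1 h the slopes of replicates 3 and 2 were 0.705 and 0.665, and 0.68 and 0.895 against the control arrays of the other times. The slopes rest on unequal sets of probe sets. Replicate 3 had 559 at 0.5 h, 3248 at 2 h and 2885 at 4 h, and replicates 1 and 2 had 79 and 65 at 0.5 h and 362 and 630 at 2 h. Control arrays of replicate 3 that are out of place at these times do not explain the whole difference, since with the control arrays of the other times as reference the slope at 2 h was still 0.474 (95% interval over probe sets 0.452 to 0.494), below the 0.803 to 1.24 of the 18 arrays of the other replicates and later times. Untreated RNA mixed into IAA 2 h replicate 3 may contribute: the share of the change reached was 0.388 in probe sets called already at 0.5 h and 0.235 in those not called at 0.5 or 1 h, a difference of 0.153 (0.0698 to 0.233), between the bounds set for either outcome. The tables argue against an exchange of the IAA 1 h and 2 h arrays of replicate 3 as the whole cause, since the array labelled 1 h had a slope of 0.245 on the 2 h change of the others, 0.113 lower (-0.113) than the array labelled 2 h and below the 0.665 to 1.27 of those 18 arrays at their own times. No biological explanation was tested, because no label sets replicate 3 apart. The control arrays of replicate 3 also lay apart from those of replicates 1 and 2 at all 8 times, as given under the other observations.

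Of 12 genes grouped after the data were seen, AT2G21640 and GSTU25 among them, 8 passed as lower on IAA at 8 h and 7 at 12 h, and the 8 not chosen by their fall had medians of -1.41 and -1.44, of which 5 and 4 passed. The tables argue against a rise on control medium alone, since over all 12 the IAA arrays of 8 and 12 h lay at -2.4 (median log2 difference) from the 0 h arrays and the control arrays at -0.518, and over the 8 alone at -1.85 (quartiles -2.88 and -1.38) and -0.436. They also argue against the scaling of the arrays, since the median of all 12 at 8 h was -1.91 as deposited and after quantile normalization, and that of the 8 was -1.46 (quartiles -2.12 and -0.934) after it. Array variation present without IAA cannot be told apart, because the control arrays had an SD of 0.694 in the median of the 8 and replicate 3 differed by 1.67 at 0 h, although all 6 medians within series at 8 and 12 h lay below 0 (-2.12 to -0.18). Camera gave p = 0.117 with an estimated correlation of 0.805 for the 8 genes at 8 h, and IAA itself stays an open explanation.

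Transcripts of the plastid genome, 69 genes found in a scan of the data, had a median change of 0.418 with IAA at 2 h, and with limma 0 of 69 passed, 0 of them even at an unadjusted p under 0.05 (camera adjusted p = 0.00291, and 0.961 with an estimated correlation). The shift may rest on single series, since the medians were 0.296, 1.15 and -0.103 in replicates 1, 2 and 3. It may also reflect array variation present without IAA, as the control arrays had an SD of 0.491 in the same median. Green shoot tissue cannot be told apart, since the mean of the 3 nuclear markers was -0.0335 (range -0.185 to 0.078), with mean levels of 7.79 for LHCB4.1, 7.86 for RCA and 6.32 for PORB, too few to decide; the samples were harvested as roots. An effect of IAA was not found by limma or with the estimated correlation, which does not exclude one.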

How the results depend on the processing

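The alternative without the 4 arrays that stand apart was chosen only after the results were seen, and the cause of the changes below was not tested. Fewer arrays or a stricter threshold can account for a lower count. Fewer arrays alone do not account for counts that rose, as without these 4 arrays or, at 0.5 and 2 h, without replicate 3 (559 and 3248). Quantile normalization, median centring (21 of 21 counts each), the filter on low values and the intensity trend (19 of 19 each) left every count within 1.5 times its value. The replicate block (same-numbered arrays correlated by 0.225 on average, others by -0.133, 19 of 24 pairs over 0.1, 39 of 48 arrays closest to their own number) moved 2 counts, the interactions of 0.5 with 4 h to 1727 and of 2 with 24 h to 872. Without the 4 arrays that stand apart, the counts were 427 at 0.5 h, 3433 at 2 h, 1567 and 1343 for the interactions, and 286 rising and 264 falling early peaks. None of these arrays is of 0.5 or 4 h, so for 427 and 1567 only the pooled spread differed, not the log2 changes. With a fold of at least 2 in addition, the counts from 0.5 to 24 h were 113, 186, 501, 896, 893, 801 and 522, the F test gave 1597 and the interactions 354 and 308. With only the 6 arrays of a time, the counts were 154 at 0.5 h, 87 at 1 h, 349 at 2 h and 824 at 24 h. With the 0 h effect subtracted they were 112, 156, 714, 1604, 1414, 969 and 546 from 0.5 to 24 h, and against IAA at 0 h 540 at 0.5 h and 1044 at 1 h. A fold of at least 1.5 gave 3610 probe sets in kinetic classes, with 361, 933 and 618 rising and 317, 894 and 487 falling at early, middle and late peaks.

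With arrays or replicate numbers left out, the counts ran from 65 to 559 at 0.5 h, 93 to 511 at 1 h, 362 to 3248 at 2 h, 1808 to 4036 at 4 h, 1444 to 3570 at 8 h, 993 to 2671 at 12 h and 613 to 1687 at 24 h. The interactions ran from 245 to 1142 and from 139 to 884, the F test from 2741 to 6810, the control course from 0 to 2 and the list pairs of the control course from 0 to 7, the last without replicate 3. Where this left a group with 2 arrays, the pooled spread was used. The 0 h comparison and each control contrast gave 0 under every alternative run. Of 1970 alternative values for 108 named results, 1834 stayed on their side of the threshold, 128 in 30 results no longer passed, 8 newly passed and 0 reversed. A reversal was counted only where the main or the alternative value passed. LBD29 at 0 h (log2 -0.23, up to 0.07) and GI at 0.5 h (0.18, down to -0.14), which never passed, did change sign. Signal over background was not modelled, and the recovery of changes near the background was not tested.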

Other observations

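The scan of 47 gene families by symbol stem and of the plastid genes, 48 in all, at 8 times (384 pairs, 20 called by camera, 5 with an estimated correlation) was made only after the data were seen, as was the search for genes called in both directions; the regroupings of the arrays were planned.

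Of 11 measured tau class glutathione transferases (GSTU), detoxifying enzymes, 5 fell at 8 h and 3 at 12 h, with medians of -0.84 and -0.64, negative under both other scalings, and camera adjusted p = 0.0162 and 0.0366 with an estimated correlation. At 24 h 1 of the 11 fell (median -0.318, adjusted p = 0.803 with an estimated correlation). GSTU25, also among the 12 genes grouped after the data were seen, fell by 2.71 at 12 h (log2, ± 0.359, adjusted p = 6.12e-07), GSTU28 fell by 1.90 ± 0.321 and GSTU27 fell by 1.55 ± 0.166 at 8 h. Of 47 UGT glycosyltransferases, 13 fell and 2 rose at 8 h (median -0.34, adjusted p = 0.292 with an estimated correlation). WRKY transcription factors (6 members) had a median of 0.54 at 0.5 h (adjusted p = 0.0401 with an estimated correlation), and none of the 6 passed at that time alone, WRKY22 having the largest change of 2.09 ± 0.572 (adjusted p = 0.0636). TUB tubulins, SWEET transporters and XTH members were lower at 2 h by the preset correlation, with adjusted p = 0.513, 0.6 and 0.0501 with an estimated one.

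Among genes with a probe set of their own, 56 were called higher at 1 time and lower at another, 23 higher first and 33 lower first. AT5G22860 was higher at 2 h (1.34) and lower at 12 h (-1.12), AT2G42060 higher at 4 h (1.36) and lower at 24 h (-1.41), and AT2G41800 lower at 4 h (-1.02) and higher at 12 h (2.12).

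For each single time, the 6 arrays make only 10 splits, too few for a share under 0.05. The real count and the highest other were 268 and 0 at 0.5 h, 442 and 2 at 1 h, 2094 and 338 at 2 h, 3827, 3385 and 2483 and each time 0 at 4, 8 and 12 h, and 1592 and 57 at 24 h, each real count being reached by 1 split; at 0 h both were 0. The control contrasts gave 0 in the real split, reached by all 10 splits, with highest others of 266 at 1 h, 69 at 2 h and 2 at 12 h, and 0 at 0.5, 4, 8 and 24 h. This points to a structure among the control arrays, which was not confined to 0, 1 and 2 h. On the second principal component of all arrays (13.6% of the variance), the replicate 3 control arrays of all 8 times lay at -3.47 or lower. Those of replicates 1 and 2 lay at -0.698 or higher. Control 0 h replicate 3, in the reference group of each control contrast, is 1 of the 4 arrays farthest from their group means. Its mean squared deviation was 0.0887, against a median of 0.036 over the arrays. Chance was unlikely for the F test, where of 100 regroupings, the real one included, only the real one reached 6429 (highest other 2083). The same held for the list pairs, where only the real one of 100 reached 26 (highest other 11). A regrouping can leave the arrays of a time as they were, so the other counts are not free of the IAA effect. In the control course the real count was 0, which all 100 of 100 regroupings had to reach (highest other 33), so this says nothing about chance.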
